A study of Mus musculus with 28 samples.

How the data were processed

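Gene expression was measured by RNA-seq in 28 libraries of YFP-positive luminal cells sorted from mouse prostates as LY6D+ or LY6D-, from wild-type and Pten-deleted mice, either hormone sensitive or castrated. RNA came from sorted cells, was amplified with a modified Smart-seq2 protocol and was sequenced as single reads, per the labels. The table holds raw counts per gene, with 1 column per library, deposited by the authors with no normalisation. Trim Galore 0.6.5, STAR 2.5.1b, the genome build GRCm38 and edgeR are named per the submitters' processing notes. The counting step, the annotation release, the strand setting and any filter are not given in the sources used here. So counts of genes that overlap on opposite strands, and of families with near-identical members such as the seminal vesicle, defensin, secretoglobin, gasdermin C and Ifi200 genes, may include shared reads. The table has 33460 Ensembl gene IDs, of which 33161 were matched to names in the GENCODE vM21 annotation of GRCm38, and the others hold 0.0313% of the counts. Gene positions come from that annotation.

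Groups were taken from the labels, giving 8 groups of genotype, hormone state and fraction, with 5 libraries in each hormone-sensitive wild-type group and 3 in the others. All 28 columns were used and none was left unassigned. Library titles carry a letter, A to E for the hormone-sensitive wild type, A, D and E for the castrated wild type and A to C for the knockout, and replicate numbers follow the letters.

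Comparisons, tests, alternatives, gene lists and the rule for named genes were set before the data were examined, and what was added later is said to be so where it appears. Counts were tested with edgeR 4.0.16 in R 4.3.3, using TMM normalisation, filterByExpr by group, a model of 8 group means over all 28 libraries and robust quasi-likelihood F tests, with Benjamini-Hochberg adjustment at 0.05 over the genes tested. The 12 comparisons set LY6D+ against LY6D-, castrated against hormone sensitive, and knockout against wild type, each within 1 level of the other factors. Another 6 contrasts tested whether pairs of these effects differ. Levels are TMM-normalised CPM, without a pseudocount.

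Named genes were the 10 highest and 10 lowest log2 fold changes of each LY6D comparison, 6 and 6 of each castration or genotype comparison and 3 and 3 of each interaction. They had to pass the test, reach a mean of 10 CPM in the higher group, have every library of the higher group above every library of the lower group, and carry a symbol other than a predicted or unnamed one. Fewer are named where fewer qualified, and Ly6d, Pten, Krt8, Krt18 and Ar were reported as label checks. Up to 4 members with the smallest adjusted p were taken from each list named in a comparison, and genes behind a count of 5 or fewer were named after their values were seen. The same rule was applied to fits added later. Where a group had 0 counts, the fold was bounded against a floor of 3 counts over the group, and with 1 to 3 counts the ratio is given with its exact conditional 95% interval.

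There were 20 gene lists: proximal luminal progenitor, distal secretory luminal, androgen response, basal epithelial, seminal vesicle, leukocyte, fibroblast and smooth muscle, endothelial, proliferation, interferon response, MHC class I, MHC class II, inflammatory (NF-kappaB), immediate early and stress, FOXO targets, cholesterol biosynthesis, endoplasmic reticulum stress and secretory pathway, squamous differentiation, glutathione and xenobiotic, and mitochondrially encoded genes. Each was tested in the 12 comparisons with camera in limma 3.58.1 on voom values, at a preset correlation of 0.01 and again with an estimated one. Adjustment was over all 240 tests in the fit of 28 libraries, and over its own, fewer tests in each later knockout or paired fit. For each list the members past the test over all genes and adjusted over the list alone were counted.

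Alternatives were RLE size factors, the 50 most abundant genes left out of library sizes, no filter, a filter of 5 CPM in 3 libraries, replicate blocks, only the groups compared, DESeq2 1.42.0, limma voom with quality weights, and each library left out in turn. Alternatives added after the data were seen were a fit without the 8 wild-type libraries of letters D and E, fits of the 12 knockout libraries with and without a replicate block, the 2 groups with a block, edgeR's newer quasi-dispersion, and paired fits over the 16 wild-type and the 12 knockout libraries. Whether LY6D+ and LY6D- libraries with the same number belong together was checked from the correlation, across genes, of their deviations from the group means. Correlations of libraries with the same number were 0.154 to 0.220 in the hormone-sensitive wild type, 0.128 to 0.333 in the castrated wild type and 0.115 to 0.234 in the castrated knockout, each above those with other numbers, so these were treated as pairs. In the hormone-sensitive knockout they were 0.052 to 0.083, also highest for the same number, and 0.173 to 0.241 over genes of at least 10 CPM, so they missed the bar set for pairs only over all genes. The fits with a replicate block and the paired knockout fit still matched these libraries by number. Genes are not independent replicates in such correlations.

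The code was tested on simulated data with the hormone-sensitive knockout LY6D comparison. The fit of 28 libraries recovered 30% of genes changed 4-fold and 71% of those changed 16-fold, with 3 false calls, and the fit of 12 knockout libraries 73% and 99%, with 12 false calls. The paired wild-type fit recovered 34% and 51%, with 2 false calls. The common biological coefficient of variation was 1.01 over the 28 libraries and 0.554 over the knockout libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.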

Results

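The series measured gene expression in luminal cells sorted from the mouse prostate, as counts of RNA-seq reads per gene in 28 libraries. Luminal cells, which line the ducts and make the prostatic secretions, were marked in mice that switch on yellow fluorescent protein (YFP) in keratin 8 cells after tamoxifen. In the wild-type mice (K8Y in the labels) tamoxifen gave YFP alone, and in the knockout mice (K8PY) it also deleted Pten, a lipid phosphatase that restrains PI3K signalling and is often lost in prostate cancer. YFP-positive cells were sorted 4 months after tamoxifen by LY6D, a GPI-anchored surface protein that the series' title ties to castration-resistant luminal progenitors, into LY6D+ and LY6D- fractions. Mice were either hormone sensitive (intact) or castrated by surgery 1 month before. Each hormone-sensitive wild-type fraction had 5 libraries, and the other 6 groups of genotype, hormone state and fraction had 3 each. Total counts per library ran from 1739527 to 28647911, and 8333 to 16604 genes had at least 5 counts. The lowest totals were 1739527 and 6127379, in replicates 3 and 2 of the castrated wild-type LY6D+ group, and 6511875 in replicate 5 of the hormone-sensitive wild-type LY6D- group. The labels do not say that replicates came from separate mice, so p-values measure the spread between these libraries, which may be technical. Levels are given as mean ± SD of normalised CPM, read counts scaled to library size, with the group named first in a comparison given first, and log2 fold changes as value ± SE, or as bare numbers beside a gene. The first adjusted p given for camera, the test of gene lists, uses a preset correlation between genes. Intervals and lower bounds on folds cover counting error only, since amplified reads are not independent molecules.

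Ly6d (chromosome 15, 74762056 to 74763620 in GRCm38, where all positions are given) was first used to check the sort label. It lay at 50.2 to 1558 CPM in the 14 LY6D+ libraries and at 0 to 32.9 CPM in the 14 LY6D- libraries, so no LY6D- library reached the lowest LY6D+ library. Pten (chromosome 19, 32757497 to 32826160) lay at 5.27 to 15.4 CPM in the 12 knockout libraries and at 0.698 to 39.1 CPM in the 16 wild-type libraries. Counts over a whole gene include exons that stay outside a deletion, so the Pten level checks the genotype label only weakly. The luminal keratin Krt8 was abundant in every library, at 919 to 4557 CPM, and Ar, the androgen receptor gene, lay at 75.3 to 201 CPM.

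Androgen withdrawal shuts down the secretory genes of the prostate and seminal vesicle, so those transcripts were read against the hormone labels. The knockout libraries followed their labels. Svs2 (chromosome 2, 164235929 to 164238466), which encodes a seminal vesicle secretory protein, lay at 5666 to 13365 CPM in hormone-sensitive LY6D+ and 138270 to 355160 CPM in hormone-sensitive LY6D- knockout libraries, and at 0.585 to 59.5 CPM in the 6 castrated ones. In the wild type, 8 of the 16 libraries did not follow, all of them carrying the letter D or E in their titles. Among libraries labelled hormone sensitive, Svs2 lay at 22959 to 460660 CPM in the 6 of letters A to C and at 0 to 1.77 CPM in the 4 of letters D and E. Among libraries labelled castrated, it lay at 2.83 and 11.2 CPM in the 2 of letter A and at 74.0 to 441240 CPM in the 4 of letters D and E. Tgm4 (chromosome 9, 123034726 to 123067561), a prostate transglutaminase, ran the same way, with 866 to 6834 CPM and 0 to 5.50 CPM under the hormone-sensitive label, and 0 and 0.942 CPM and 177 to 12414 CPM under the castrated label. Transcripts of the 8 seminal vesicle genes took up to 51.5% of the counts of a library. For wild-type libraries, hormone sensitive and castrated therefore stand for the label alone, here and below, and every comparison kept the labels as given.

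**Figure D1:**
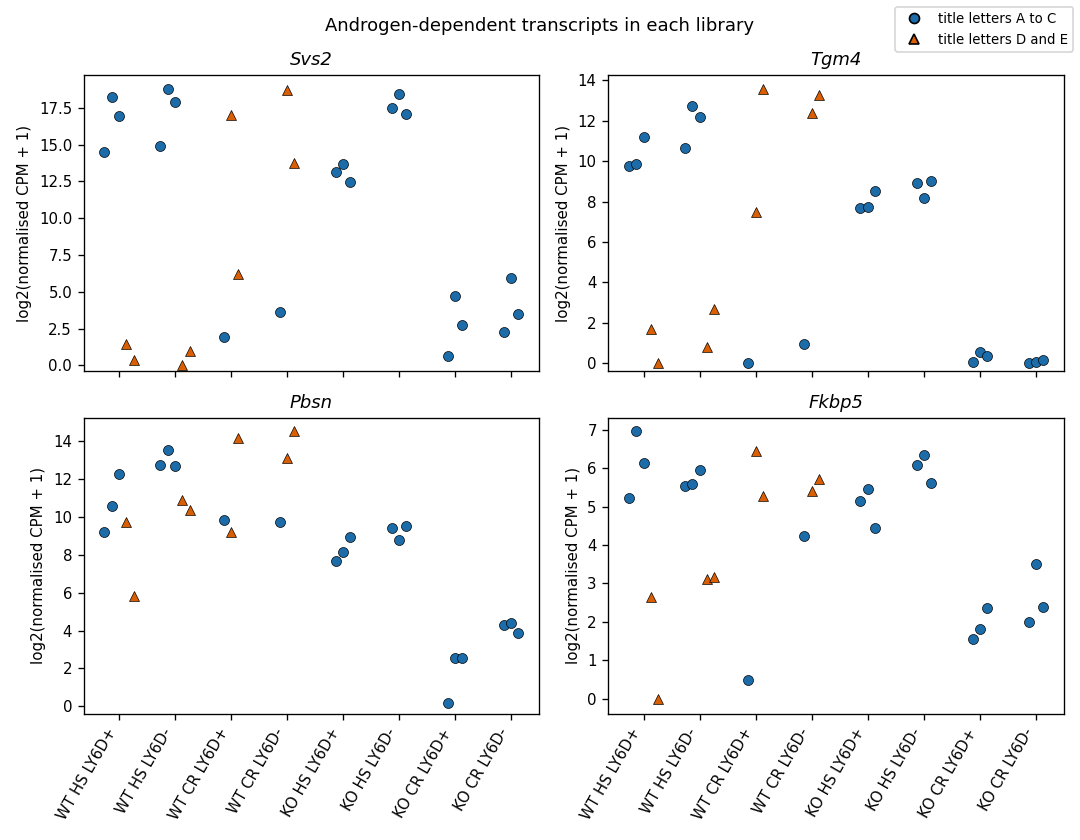
Svs2, Tgm4, Pbsn and Fkbp5 in each of the 28 libraries, as log2 of normalised CPM plus 1 on the y axis and the 8 groups on the x axis, with blue circles for title letters A to C and orange triangles for D and E. In the wild type the orange triangles of Svs2 lie at 0 to 1.77 CPM under the hormone-sensitive label and at 74.0 to 441240 CPM under the castrated label, opposite to the blue circles.

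LY6D+ cells labelled hormone-sensitive wild type (n = 5 per fraction) carried more Dcn and Lrp4 and less Scamp1 than LY6D- cells. Dcn (chromosome 10, 97479609 to 97518143), the matrix proteoglycan decorin, lay at 536 ± 123 against 55.3 ± 24.9 CPM (log2 fold change 3.28 ± 0.57, edgeR adjusted p = 0.0264). Lrp4 (chromosome 2, 91457511 to 91513779), a receptor of the LDL family, lay at 50.9 ± 12.02 against 6.21 ± 3.76 CPM (log2 fold change 3.04 ± 0.51, edgeR adjusted p = 0.0205). Scamp1 (chromosome 13, 94201310 to 94285857), a protein of secretory carrier membranes, lay at 130.0 ± 15.96 against 273 ± 50.7 CPM (log2 fold change -1.07 ± 0.19, edgeR adjusted p = 0.0293). Keratins of basal epithelium, the layer under the luminal cells, had large fold changes without passing the test over all genes. Krt5 (chromosome 15, 101707070 to 101712898) lay at 146 ± 55.7 against 4.74 ± 3.41 CPM (log2 fold change 4.93 ± 1.05, edgeR adjusted p = 0.101). Krt14 (chromosome 11, 100203162 to 100207548) lay at 334 ± 187 against 5.64 ± 5.77 CPM (log2 fold change 5.88 ± 1.52, edgeR adjusted p = 0.213). Of the 14 basal epithelial genes, 0 passed over all genes and 9 were higher when adjusted over the list alone (camera adjusted p = 7.82e-09, and adjusted p = 0.321 with an estimated correlation). Of the endothelial markers 5 of 12 were higher adjusted over the list alone and 0 over all genes, with Pecam1 at 32.7 ± 44.7 against 2.28 ± 3.51 CPM. Camera gave endothelial genes adjusted p = 8.54e-07, and adjusted p = 0.321 with an estimated correlation. Of the leukocyte genes 1 of 17 was higher and 1 lower, adjusted over the list alone, and of the fibroblast and smooth muscle genes 1 of 13 (Dcn) was higher in both counts. Over 18222 genes tested, edgeR called 4 higher and 3 lower in LY6D+, and 19 genes with the replicate pairs as a block. The count fell to 0 without LY6D+ replicate 5 or LY6D- replicate 2, to 1 without LY6D+ replicate 2 and to 3 without LY6D+ replicate 1 or LY6D- replicate 3 or 5, and rose to 18 without LY6D+ replicate 4. DESeq2 called 404, limma voom with quality weights 6, and a fit without the 8 libraries of letters D and E, added after the data were seen, 177.

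Libraries labelled castrated wild type (n = 3 per fraction) had higher mean levels of basal transcripts in LY6D+, with no gene past the test over all genes. Trp63 (chromosome 16, 25683763 to 25892102), the transcription factor that marks basal cells, lay at 177 ± 141 against 2.48 ± 2.98 CPM (log2 fold change 6.19 ± 1.83, edgeR adjusted p = 0.362). Lamb3, a laminin chain of hemidesmosomes, had a log2 fold change of 4.91 (edgeR adjusted p = 0.0702). Of the 14 basal genes 0 passed over all genes and 10 were higher adjusted over the list alone (camera adjusted p = 7.24e-08, and adjusted p = 0.330 with an estimated correlation). Fibroblast and smooth muscle genes leaned the same way, with 2 of 13 higher adjusted over the list alone, 0 over all genes, and Dcn at 828 ± 389 against 97.3 ± 63.3 CPM. Camera gave fibroblast and smooth muscle genes adjusted p = 0.000368, and adjusted p = 0.380 with an estimated correlation. The endothelial list had 0 of 12 past either adjustment and a median of 2.41, or 0.88 with genes at 0 counts set to their bound (camera adjusted p = 0.00580, and adjusted p = 0.567 with an estimated correlation). EdgeR called 0 genes, with 1631 at an unadjusted p under 0.05, and 1 gene with the replicate pairs as a block, where DESeq2 called 508 and limma voom with quality weights 0. Without LY6D+ replicate 1, 2 or 3 edgeR called 853, 3 and 2, and without LY6D- replicate 1 it called 17. With RLE size factors it called 5, and these moved the median log2 fold change of all genes from -0.25 to -0.13.

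The 16 wild-type libraries form 8 pairs of LY6D+ and LY6D- libraries with the same title letter and label, and a fit over those pairs, added after the data were seen, does not depend on which label is right. In it LY6D+ cells were higher in 8 of 8 pairs for Krt5, Krt14 and Trp63. Krt5 lay at 136 ± 65.7 against 4.52 ± 2.65 CPM, log2 fold change 5.05 ± 0.62, edgeR adjusted p = 0.0138. Krt14 lay at 295 ± 182 against 5.51 ± 4.97 CPM, log2 fold change 6.22 ± 0.90, edgeR adjusted p = 0.0284, and Trp63 at 119.9 ± 95.4 against 4.44 ± 6.81 CPM, log2 fold change 6.06 ± 0.92, edgeR adjusted p = 0.0321. Also higher in 8 of 8 pairs were Dcn at log2 fold change 3.33 and the related proteoglycans Prelp at 6.21 and Fmod at 5.02, with Pdpn, the surface glycoprotein podoplanin, at 4.68 (edgeR adjusted p = 0.0138, 0.0141, 0.0138 and 0.0138). Lower in LY6D+ in 8 of 8 pairs were Sdf2l1 and Ero1lb, which serve protein folding in the endoplasmic reticulum, at -1.25 and -1.46, Srpr, a receptor subunit for the signal recognition particle, at -0.68 and Scamp1 at -1.18 (edgeR adjusted p = 0.0260, 0.0324, 0.0321 and 0.0349). Of the basal list 4 of 13 genes rose over all genes and 9 adjusted over the list alone (camera adjusted p = 6.72e-19, and adjusted p = 0.00251 with an estimated correlation). Other cell type lists lay higher in LY6D+ by camera too, the endothelial list with a median of 3.45 against 4.13 for basal genes, and with 0 of 12 over all genes and 1 adjusted over the list alone. Camera gave endothelial genes adjusted p = 4.25e-06, and adjusted p = 0.191 with an estimated correlation. Of the fibroblast and smooth muscle list 1 of 13 rose over all genes and 3 adjusted over the list alone (camera adjusted p = 2.51e-05, and adjusted p = 0.162 with an estimated correlation). The leukocyte list had 0 of 15 past either adjustment and a median of -0.13 (camera adjusted p = 3.73e-05, and adjusted p = 0.199 with an estimated correlation). Of the endoplasmic reticulum list 1 of 18 fell and 12 were lower adjusted over the list alone (camera adjusted p = 2.89e-11, and adjusted p = 0.119 with an estimated correlation). Of the progenitor list 1 of 14 rose and 6 were higher adjusted over the list alone (camera adjusted p = 3.73e-05, and adjusted p = 0.199 with an estimated correlation). Of the squamous differentiation list 1 of 10 rose (Sprr1a, at 0.74) and 2 adjusted over the list alone (camera adjusted p = 7.61e-05, and adjusted p = 0.0230 with an estimated correlation). Of the seminal vesicle list 0 of 8 passed over all genes and 3 were lower adjusted over the list alone (camera adjusted p = 1.02e-18, and adjusted p = 0.00197 with an estimated correlation). This fit called 33 genes higher and 6 lower of 16415 tested.

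**Figure D2:**
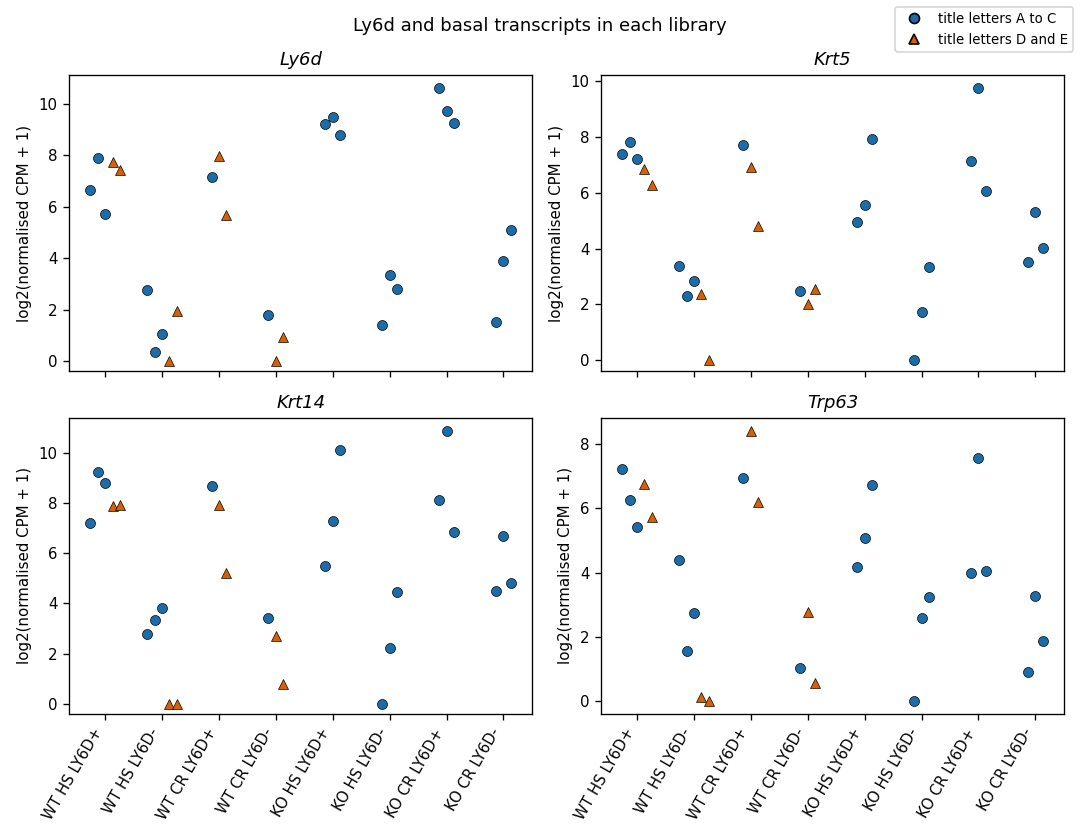
Ly6d, Krt5, Krt14 and Trp63 in each of the 28 libraries, as log2 of normalised CPM plus 1 on the y axis and the 8 groups on the x axis, with blue circles for title letters A to C and orange triangles for D and E. Ly6d lies at 50.2 to 1558 CPM in LY6D+ and 0 to 32.9 CPM in LY6D- libraries, and the basal transcripts are higher in the LY6D+ groups.

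In hormone-sensitive knockout prostates (n = 3 per fraction) LY6D+ cells were higher in genes of the progenitor, inflammatory and basal lists and in Igfbp2 and Olfm4, and lower in Adam23, Avpr1a and seminal vesicle transcripts. Olfm4 (chromosome 14, 79984081 to 80023139), a secreted glycoprotein of epithelial stem and progenitor cells, lay at 1389 ± 924 against 15.2 ± 5.78 CPM (log2 fold change 6.51 ± 0.88, edgeR adjusted p = 0.00516). Igfbp2 (chromosome 1, 72824503 to 72852474) and Igfbp3, which bind insulin-like growth factors, had log2 fold changes of 7.55 and 3.86 (edgeR adjusted p = 0.0198 and 0.0282). The receptor phosphatase Ptpru lay at 5.06, Ltbp1, which anchors latent TGF-beta in matrix, at 5.53, and Ccn2, a matrix-associated growth regulator, at 4.91 (edgeR adjusted p = 0.00211, 0.0371 and 0.0235). Lowest in LY6D+ were Adam23 (-7.32), a disintegrin, the vasopressin receptor Avpr1a (-6.32), Ptgds (-5.90), a prostaglandin synthase, and the defensin Defb30 (-5.11; edgeR adjusted p = 0.0172, 0.0311, 0.0478 and 0.00902). Galnt14, Tagln, Cd200r3 and Itprid1 were also among the 10 highest, at 6.27, 4.42, 3.96 and 3.77, and Lmo3, Svs5, Mrgpra3, Nefh, Tmed6 and Defb42 among the 10 lowest, at -5.01 to -4.50. These values come from a fit of the 12 knockout libraries alone, chosen after the data were seen, which called 492 genes higher and 449 lower of 16159, while the 2 groups alone gave 703 and 592 of 14223. The genes named had edgeR adjusted p = 0.306 to 1 in the fit of 28 libraries. The fit of all 28 libraries, set before, called 0 of 18222 with edgeR, with 899 at an unadjusted p under 0.05, but 23 higher and 38 lower with libraries of the same number as a block. DESeq2 called 172 and limma voom with quality weights 1520.

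By group, 6 of the 14 proximal luminal progenitor genes rose in LY6D+ hormone-sensitive knockout cells and 11 adjusted over the list alone. Among them were Wfdc2 (2.35), a whey acidic protein, Gsto1 (2.42), a glutathione transferase, and Tacstd2 (1.11), the surface protein TROP2 (edgeR adjusted p = 0.00403, 0.0120 and 0.01003). The list's camera adjusted p = 6.08e-10 became adjusted p = 0.107 with an estimated correlation. Among the 16 distal secretory genes 3 fell and 1 rose over all genes, and 8 were lower and 1 higher adjusted over the list alone (camera adjusted p = 7.28e-06, and adjusted p = 0.165 with an estimated correlation). Trpv6, a calcium channel, Dpp4, a surface peptidase, and Azgp1, a secreted glycoprotein, fell by 3.40, 1.74 and 1.36 on the log2 scale, and Bace2 rose by 1.29. Basal genes rose in 4 of 14 over all genes and 12 adjusted over the list alone, with Lamb3 at 3.25 and Lama3 at 2.76 (camera adjusted p = 3.62e-05, and adjusted p = 0.554 with an estimated correlation). Of 20 inflammatory genes 8 rose, 9 higher and 1 lower adjusted over the list alone, including Cxcl15 (2.21), Cxcl17 (1.97), Tnf (1.57) and Cxcl16 (1.21). Camera gave inflammatory genes adjusted p = 1.28e-05, and adjusted p = 0.0870 with an estimated correlation. Interferon genes rose in 1 of 19, also adjusted over the list alone (camera adjusted p = 3.7e-06, and adjusted p = 0.554 with an estimated correlation). Seminal vesicle transcripts fell in 2 of 7 genes and 6 adjusted over the list alone, with Pate4 at 539.6 ± 165 against 12012 ± 6419 CPM (log2 fold change -4.48 ± 0.75, edgeR adjusted p = 0.0107). Reads may be shared within this gene family. Camera gave seminal vesicle genes adjusted p = 2.56e-08, and adjusted p = 0.188 with an estimated correlation. The leukocyte median was 0.93 (camera adjusted p = 0.0502, and adjusted p = 0.735 with an estimated correlation). Leukocyte and endothelial genes had 0 members past either adjustment, and fibroblast and smooth muscle genes 1 of 13 (Tagln) over all genes and 2 adjusted over the list alone.

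LY6D+ cells of castrated knockout prostates (n = 3 per fraction) were higher in Krt15, Trim29 and genes of the progenitor and basal lists, and lower in Edn3, Slc26a3 and genes of the secretory list. Krt15 (chromosome 11, 100131758 to 100135928), a keratin of basal and stem cells, lay at 2224 ± 1737 against 172 ± 44.3 CPM (log2 fold change 3.70 ± 0.67, edgeR adjusted p = 0.0237). Trim29, a basal-type TRIM protein, had a log2 fold change of 4.43, the FGF receptor Fgfr3 3.92, the desmosomal plakophilin Pkp1 3.56 and Aldh3a1, an aldehyde dehydrogenase, 3.38 (edgeR adjusted p = 0.0476, 0.0178, 0.0297 and 0.0285). Edn3 (chromosome 2, 174760619 to 174784042), an endothelin, had a log2 fold change of -7.32, the chloride exchanger Slc26a3 -7.27, the chloride channel Clcnkb -6.14 and the proton pump subunit Atp6v1g3 -5.91 (edgeR adjusted p = 0.0124, 0.0231, 0.00698 and 0.00526). Cyp4a12a, a fatty acid hydroxylase, was higher in LY6D- by a ratio of 1075 (95% interval 297 to 8879.6) from 2192 against 2 counts (edgeR adjusted p = 0.00343). Of the progenitor list 3 of 14 rose (Krt4 2.41, Gsto1 2.39 and Krt7 1.19), 8 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000285, and adjusted p = 0.300 with an estimated correlation). The basal list had 1 of 14 higher and 12 adjusted over the list alone (camera adjusted p = 5.9e-08, and adjusted p = 0.390 with an estimated correlation). The squamous list had 1 of 10 higher (Dsc2, 1.24) and 5 adjusted over the list alone (camera adjusted p = 3.53e-05, and adjusted p = 0.257 with an estimated correlation). The secretory list had 3 of 16 lower (Defb50 -6.69, Mme -2.10 and Azgp1 -1.92) and 10 adjusted over the list alone (camera adjusted p = 0.000234, and adjusted p = 0.188 with an estimated correlation). Leukocyte and fibroblast and smooth muscle genes had 0 members past either adjustment, and endothelial genes 1 of 7 higher and 1 lower adjusted over the list alone. The leukocyte median was 0.75 (camera adjusted p = 0.00410, and adjusted p = 0.554 with an estimated correlation). These values come from the same later fit of the 12 knockout libraries, where 64 genes were higher and 172 lower of 16159. The genes named had edgeR adjusted p = 0.689 to 1 in the fit of 28 libraries, and the 2 groups alone gave 0 of 14750 in edgeR (1755 at an unadjusted p under 0.05). The 28 libraries gave 0 of 18222 (617 unadjusted), 4 with the replicate pairs as a block and 2 without LY6D- replicate 3. DESeq2 called 129 and limma voom with quality weights 566.

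A fit over the 6 pairs of knockout libraries with the same number and label, added after the data were seen, called 661 genes higher and 578 lower in LY6D+ of 16159, although the hormone-sensitive pairs missed the bar set for pairs over all genes. In 6 of 6 pairs LY6D+ was higher for Krt5, at 229.9 ± 317 against 12.6 ± 13.9 CPM (log2 fold change 4.24 ± 0.59, edgeR adjusted p = 0.00870), Krt14, at 587 ± 727 against 29.3 ± 37.5 CPM (log2 fold change 4.60 ± 0.72, edgeR adjusted p = 0.0126), and Trp63, at 62.1 ± 70.3 against 4.25 ± 3.70 CPM (log2 fold change 3.84 ± 0.54, edgeR adjusted p = 0.00957). Of the basal list 12 of 14 genes rose over all genes and 14 adjusted over the list alone (camera adjusted p = 2.71e-15, and adjusted p = 0.120 with an estimated correlation). Squamous genes rose in 6 of 10, and 8 adjusted over the list alone (camera adjusted p = 2.81e-06, and adjusted p = 0.120 with an estimated correlation). Progenitor genes rose in 9 of 14, and 9 adjusted over the list alone (camera adjusted p = 6.8e-09, and adjusted p = 0.244 with an estimated correlation). Interferon genes rose in 4 of 19, and 10 adjusted over the list alone (camera adjusted p = 5.09e-09, and adjusted p = 0.365 with an estimated correlation). Secretory genes fell in 9 of 16, with 10 lower and 1 higher adjusted over the list alone (camera adjusted p = 6.1e-09, and adjusted p = 0.120 with an estimated correlation). Leukocyte, endothelial and fibroblast and smooth muscle genes had 0 members past either adjustment (camera adjusted p = 0.00556, 0.492 and 0.00218, and adjusted p = 0.557, 0.620 and 0.365 with an estimated correlation).

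No gene passed the edgeR test in the same direction in all 4 LY6D comparisons of the 28-library fit, where DESeq2 gave 3 higher and limma voom with quality weights 0. In the knockout libraries alone the hormone-sensitive and castrated LY6D comparisons, which share no library, had 42 higher genes in common where independent lists of the same sizes would share 1.95, and 61 lower genes where they would share 4.78.

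Castration of knockout mice (n = 3 per group) was followed by large falls of secretory transcripts in both fractions. In LY6D- cells Svs2 lay at 24.5 ± 30.5 against 225300 ± 114620 CPM (log2 fold change -13.18 ± 1.77, edgeR adjusted p = 0.00223) and Tgm4 had a log2 fold change of -12.98 (edgeR adjusted p = 2.45e-05). LY6D+ cells had Tgm4 at 0.263 ± 0.222 against 261 ± 95.8 CPM (log2 fold change -9.95 ± 0.64, edgeR adjusted p = 2.57e-05). Fkbp5, a chaperone partner induced by the androgen receptor, had a log2 fold change of -3.52 there and the zinc finger gene Zbtb16 -4.29 (edgeR adjusted p = 0.00430 and 0.00450). Abo, a blood group glycosyltransferase, was at least 2108-fold lower and Tcaf3, a regulator of TRP channels, at least 2617-fold lower in castrated LY6D+ cells (edgeR adjusted p = 2.57e-05 and 0.000164). The protease inhibitor Spink1 had log2 fold changes of -13.09 and -12.83 in LY6D+ and LY6D-, and Scgb2b7, a secretoglobin, was at least 3343-fold lower in LY6D-. Rgs5, a regulator of G protein signalling, was higher after castration in LY6D+ by 6.95 and in LY6D- by a ratio of 2217 (95% interval 613 to 18309) from 6565 against 2 counts (edgeR adjusted p = 0.0173 and 0.00574). Necab1, a calcium-binding protein, was higher in LY6D+ by a ratio of 941 (95% interval 169 to 37186) from 1180 against 1 counts and in LY6D- at least 318-fold (edgeR adjusted p = 0.00334 and 0.00147). In LY6D+ the squamous keratin Krt13 lay at 5.10 and Dapl1 at 6.56 (edgeR adjusted p = 0.0383 and 0.00114). The remaining genes of the 6 highest and lowest were Chil3 (at least 249-fold) and Bbox1 (4.87) up, and Agtr1a (at least 811-fold) and Sbpl (at least 5094-fold) down in LY6D+. Cyp4a12a was lower there by a ratio of 5811 (95% interval 1608 to 47991) from 9265 against 2 counts. In LY6D- they were Col8a1 (at least 292-fold), Syt1 (at least 213-fold), Ugt2b34 (7.82) and Snap25 (7.54) up, and Scgb2b20 (at least 1013-fold) and Svs5 (-13.72) down. These values come from the fit of the 12 knockout libraries, chosen after the data were seen, which called 98 genes higher and 284 lower in LY6D+, and 470 higher and 571 lower in LY6D-, of 16159. In the fit of 28 libraries the genes named had edgeR adjusted p = 0.255 to 1 in LY6D+ and 0.536 to 0.881 in LY6D-. The 2 groups alone gave 67 and 180 in LY6D+ and 371 and 473 in LY6D-.

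By group, 10 of 16 distal secretory genes fell in LY6D+ cells of castrated knockout mice and 8 in LY6D-, with 14 and 9 adjusted over the list alone. Camera gave secretory genes adjusted p = 8.11e-10 and 9.07e-10, and adjusted p = 0.0870 in both with an estimated correlation. Seminal vesicle genes fell in 4 of 7 and 5 of 7, and in 4 and 7 adjusted over the list alone (camera adjusted p = 0.000455 and 6.67e-09, and adjusted p = 0.408 and 0.186 with an estimated correlation). Other androgen response genes went both ways, with 5 of 22 lower and 1 higher (Steap4, a metalloreductase, 2.12) in LY6D+ and 4 lower and 3 higher in LY6D-. Adjusted over the list alone, 5 were lower and 1 higher, and 6 lower and 5 higher. Camera gave androgen response genes adjusted p = 0.00709 and 0.788, and adjusted p = 0.165 and 0.839 with an estimated correlation. In LY6D+ the progenitor list had 4 of 14 lower and 6 adjusted over the list alone, among them Psca (-4.77), a GPI-anchored surface protein, and Wfdc2 (-1.80). Camera gave progenitor genes adjusted p = 2e-05, and adjusted p = 0.188 with an estimated correlation. In LY6D- inflammatory genes rose in 6 of 20, 9 higher and 1 lower adjusted over the list alone, including Cxcl5 (4.03), C3 (3.17), Ccl20 (2.30) and Cxcl17 (1.84). Camera gave inflammatory genes adjusted p = 0.00525, and adjusted p = 0.188 with an estimated correlation. The castration comparisons in LY6D+ and LY6D- shared 55 higher genes against 2.85 for independent lists and 163 lower genes against 10.04, with no library in common, though the number for independent lists ignores the correlation of libraries of the same number. In the fit of 28 libraries edgeR called 1 gene in LY6D+, the unnamed locus 5430419D17Rik (log2 fold change -10.23 ± 1.66, edgeR adjusted p = 0.0495), and 4 in LY6D-. Those 4 were named after their values were seen. Net1 (chromosome 13, 3882018 to 3918220), a Rho exchange factor, lay at 368 ± 103 against 99.4 ± 15.7 CPM (log2 fold change 1.89 ± 0.33, edgeR adjusted p = 0.0398). Aldh6a1 (chromosome 12, 84430717 to 84451004), an enzyme of valine breakdown, lay at 68.6 ± 5.58 against 236 ± 25.9 CPM (log2 fold change -1.78 ± 0.32, edgeR adjusted p = 0.0398). The other two, 5430419D17Rik and 2010007H06Rik, had log2 fold changes of -9.01 and -4.85 (edgeR adjusted p = 0.0398 and 0.0398). Aldh6a1 and 2010007H06Rik overlap exons on the opposite strand, and the strand used in counting is not given in the sources used here. Both counts fell to 0 without any 1 of the 6 libraries compared, while DESeq2 called 173 and 227 genes and limma voom with quality weights 565 and 1536.

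Between wild-type libraries labelled castrated and hormone sensitive (n = 3 and 5), almost nothing passed the test. In LY6D+ 1 gene passed, Ablim2, an actin-binding protein named after its value was seen, which had 0 counts under the hormone-sensitive label and 13.5 ± 22.6 CPM under the castrated label (edgeR adjusted p = 0.0208). The SD shows that most of this level came from 1 library of 3, and without replicate 3, which has the lowest total, the adjusted p was 0.162; nor did it pass without hormone-sensitive replicate 5. In LY6D- 0 genes passed in edgeR, with 702 at an unadjusted p under 0.05, where DESeq2 called 122 and limma voom with quality weights 2. Of the secretory, seminal vesicle and androgen response lists 0 members passed over all genes or adjusted over the list alone in either fraction, and the list medians of the seminal vesicle genes were 3.97 and 2.32 in log2, towards the castrated label. Interferon genes had a median of 1.56 in LY6D- with 0 of 19 past either adjustment (camera adjusted p = 0.000735, and adjusted p = 0.620 with an estimated correlation). The LY6D+ count of 1 became 1041 without the replicate 1 library labelled castrated, which bears the letter A, 2 without replicate 2 and 0 without replicate 3. Without a library labelled hormone sensitive it was 8 (replicate 2 or 3), 5 (replicate 1 or 4) or 0 (replicate 5), and DESeq2 called 671 and limma voom with quality weights 0. With the 8 libraries of letters D and E left out, a choice made after the data were seen that leaves 1 castrated library per fraction, assumed to vary like the other groups, the counts were 107 higher and 40 lower in LY6D+ and 29 and 22 in LY6D-.

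Loss of Pten in LY6D+ cells under the hormone-sensitive label (knockout n = 3, wild type n = 5) came with high levels of genes that the wild type barely expressed. Of the 5 wild-type libraries of each fraction, 2 were those of letters D and E, with Svs2 at 0 to 1.77 CPM. Olfm4 lay at 1389 ± 924 CPM in the knockout, a ratio of 48965 (95% interval 16754 to 237440) from 88629 against 3 counts (edgeR adjusted p = 0.00379). Reg3b (chromosome 6, 78370657 to 78373466), an antimicrobial lectin of the gut, was at least 2358-fold higher and Atoh1 (chromosome 6, 64729125 to 64731245), a transcription factor of secretory lineages, at least 2048-fold (edgeR adjusted p = 0.00116 and 0.0101). Lypd8, a GPI-anchored antibacterial protein, was at least 6693-fold higher and Ifit1bl1, an IFIT family member, at least 5397-fold (edgeR adjusted p = 0.00581 and 0.00379). Sval1, a seminal vesicle antigen-like gene, lay at 264 ± 136 against 0.0400 ± 0.0894 CPM (log2 fold change 12.55 ± 1.51, edgeR adjusted p = 0.000101). Lower in the knockout were Bex4 (chromosome X, 136138996 to 136140443; -4.04), Rasl11b (-3.14), a Ras-like GTPase, Ngef (-3.09) and Rasgrf1 (-2.80), both exchange factors, Tbx3os1 (-2.62), antisense to Tbx3, and Hpgd (-2.49), which breaks down prostaglandins (edgeR adjusted p = 0.00647, 0.0162, 0.00581, 0.0394, 0.0242 and 0.00405). Of 19 interferon response genes 6 rose and 16 adjusted over the list alone. Usp18 (chromosome 6, 121245906 to 121270917), which removes ISG15, lay at 242 ± 57.4 against 8.08 ± 6.14 CPM (log2 fold change 4.89 ± 0.66, edgeR adjusted p = 0.000231), and others were Rsad2 (8.14), Ifit3 (7.86) and Bst2 (2.62). Camera gave interferon genes adjusted p = 9.89e-13, and adjusted p = 0.321 with an estimated correlation. MHC class I genes rose in 4 of 9 and 6 adjusted over the list alone, with Tap1 at 2.03, H2-D1 at 1.73, H2-K1 at 1.33 and Tapbp at 1.23. Camera gave MHC class I genes adjusted p = 1.17e-05, and adjusted p = 0.380 with an estimated correlation. Progenitor genes rose in 2 of 14 (Wfdc2 3.66 and Clu 2.09) and 4 adjusted over the list alone (camera adjusted p = 5.46e-05, and adjusted p = 0.330 with an estimated correlation). Endothelial, leukocyte and fibroblast and smooth muscle genes had 0 members past either adjustment, and endothelial genes a median log2 fold change of -3.54 (camera adjusted p = 0.00140, and adjusted p = 0.523 with an estimated correlation). EdgeR called 224 genes higher and 50 lower of 18222, 97, 92 and 138 in all without knockout replicate 1, 2 or 3 and 165 without wild-type replicate 5, and the 2 groups alone gave 69 and 13. DESeq2 called 537 higher and 413 lower, and limma voom with quality weights 948 and 442. Without the 8 libraries of letters D and E it was 955.

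In LY6D- cells under the hormone-sensitive label the knockout (n = 3) was higher in Ccl28, Ccl20, Wfdc18 and Dmbt1 than the wild type (n = 5, of which 2 of letters D and E). Ccl28 (chromosome 13, 119623819 to 119654359), a mucosal chemokine, was at least 641-fold higher, and the potassium channel Kcnh6 at least 415-fold (edgeR adjusted p = 0.00952 and 0.0324). Ccl20 (chromosome 1, 83116766 to 83119167), a chemokine that draws CCR6 cells, lay at 34.0 ± 13.9 CPM, a ratio of 3552 (95% interval 637 to 140380) from 1952 against 1 counts (edgeR adjusted p = 0.00327). Wfdc18, a whey acidic protein, lay at 724 ± 403 against 0.821 ± 1.22 CPM (log2 fold change 9.70 ± 1.60, edgeR adjusted p = 0.00575). Dmbt1, a mucosal scavenger receptor, had a log2 fold change of 8.94, and Havcr1, a phosphatidylserine receptor, a ratio of 1051 (95% interval 359 to 5099.6) from 1732 against 3 counts. Lower were Rbms3 (-3.65), Gas6 (-3.47), a ligand of TAM receptors, Amotl2 (-2.52), Mllt6 (-2.26), Ndrg2 (-2.17) and Znrf3 (-1.52), a ligase that restrains WNT receptors (edgeR adjusted p = 0.0446, 0.0335, 0.0418, 0.0107, 0.0352 and 0.0353). Interferon genes rose in 1 of 19 (Usp18, 2.93) and 12 adjusted over the list alone (camera adjusted p = 1.89e-07, and adjusted p = 0.462 with an estimated correlation). Of the leukocyte genes 1 of 17 was higher adjusted over the list alone. Immediate early genes were lower in 0 of 16 over all genes and 7 adjusted over the list alone (camera adjusted p = 9.88e-06, and adjusted p = 0.321 with an estimated correlation). EdgeR called 65 genes higher and 9 lower of 18222, and the total of 74 fell to 15, 14 and 22 without knockout replicate 1, 2 or 3, and to 24, 34, 46, 16 and 19 without wild-type replicate 1, 2, 3, 4 or 5. Limma voom with quality weights called 651 higher and 161 lower, while in DESeq2 the balance turned, with 239 higher and 247 lower. The 2 groups alone gave 17, and the fit without the libraries of letters D and E 152.

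**Figure D3:**
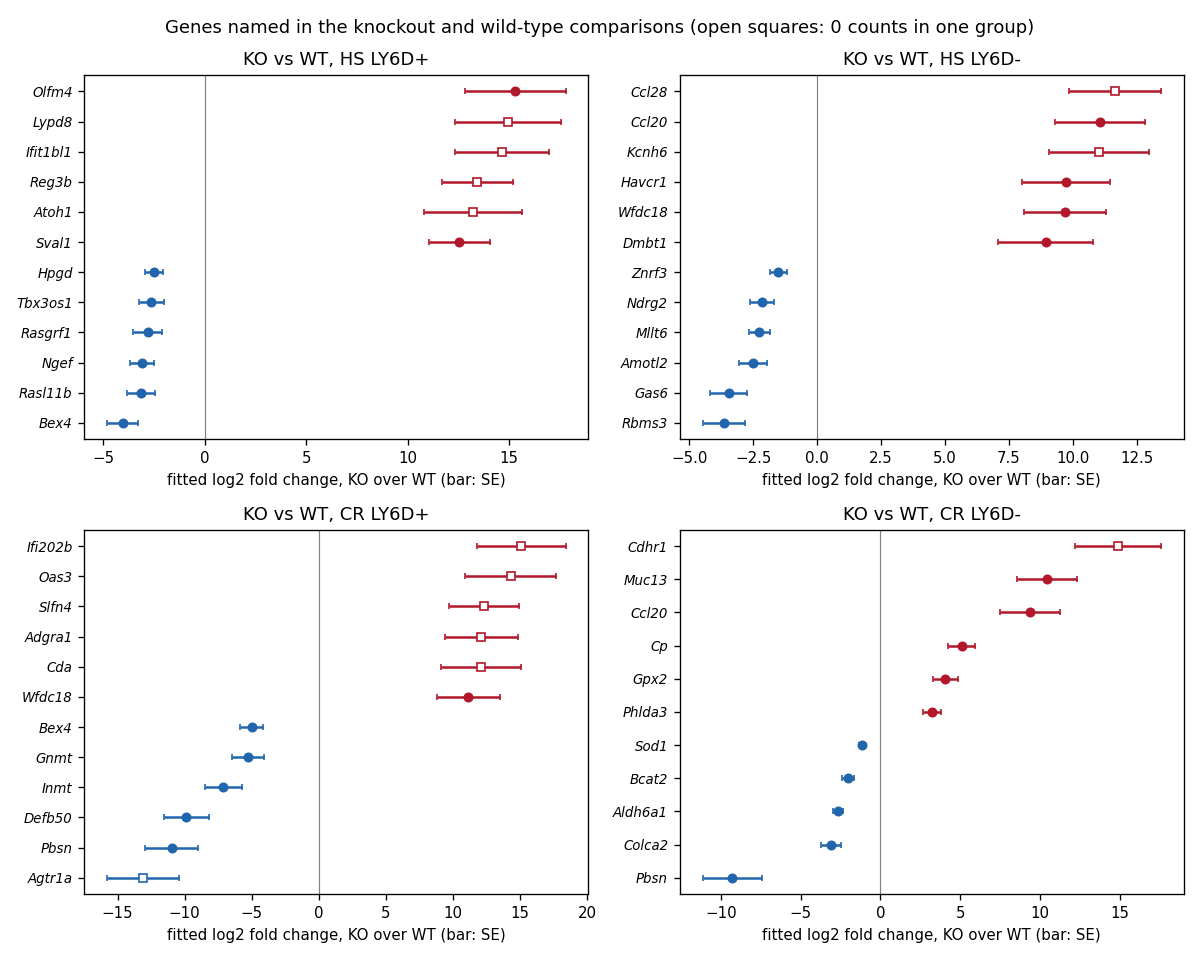
Fitted log2 fold changes of knockout over wild type (x axis, bars for ± SE) of the genes named in the 4 genotype comparisons, with open squares for genes that had 0 counts in 1 group, whose fitted value is no bound. Olfm4 and Lypd8 lie farthest to the right in hormone-sensitive LY6D+ cells, and Aldh6a1, Bcat2 and Sod1 lie on the lower side in castrated LY6D- cells.

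Under the castrated label (n = 3 per group), 2 of the 3 wild-type libraries of each fraction were those of letters D and E, with Svs2 at 74.0 to 441240 CPM. In LY6D+ cells the knockout was higher in Ifi202b, Oas3 and Slfn4, which interferons induce, Ifi202b at least 2125-fold, Oas3 at least 1206-fold and Slfn4 at least 301-fold (edgeR adjusted p = 0.0266, 0.0382 and 0.0301). Wfdc18 lay higher at 11.14 and Ccl20 by a ratio of 1732 (95% interval 311 to 68424) from 4579 against 1 counts (edgeR adjusted p = 0.0188 and 0.0183). Adgra1 and Cda were at least 267- and 263-fold higher. Pbsn (chromosome X, 77837901 to 77853623), the androgen-driven probasin gene, was lower at 3.26 ± 2.71 against 6587 ± 10134 CPM (log2 fold change -10.98 ± 1.97, edgeR adjusted p = 0.00651). Also lower were Defb50 at -9.89, Inmt and Gnmt, both methyltransferases, at -7.12 and -5.28, Bex4 at -5.02 and Agtr1a at least 1414-fold lower (edgeR adjusted p = 0.00425, 0.00856, 0.0238, 0.00321 and 0.0143). MHC class I genes rose in 4 of 9 and 7 adjusted over the list alone, with Psmb9 at 2.40, Psmb8 at 2.06, H2-D1 at 1.67 and Tapbp at 1.25. Camera gave MHC class I genes adjusted p = 0.00693, and adjusted p = 0.599 with an estimated correlation. Squamous genes rose in 2 of 10 (Sbsn 4.42 and Dsc2 2.20) and 3 adjusted over the list alone (camera adjusted p = 0.0154, and adjusted p = 0.387 with an estimated correlation). Interferon list genes had 0 of 19 past the test over all genes and 6 adjusted over the list alone, seminal vesicle genes 0 and all 8 lower, and secretory genes 2 of 16 lower and 7. Leukocyte, endothelial and fibroblast and smooth muscle genes had 0 past either adjustment. Camera gave leukocyte genes adjusted p = 0.0130, and adjusted p = 0.677 with an estimated correlation. EdgeR called 142 genes higher and 59 lower, 108 and 74 with RLE size factors, and 123 and 175 without the 8 libraries of letters D and E, so the balance of higher and lower genes turned there. DESeq2 gave 760 and 524, and limma voom with quality weights 180 and 58. RLE size factors moved the median log2 fold change of all genes from 0.23 to 0.12. The total of 201 became 1383, 133 and 125 without wild-type replicate 1, 2 or 3 and 53, 120 and 80 without knockout replicate 1, 2 or 3, and the 2 groups alone gave 2, with 1303 at an unadjusted p under 0.05.

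In LY6D- cells under the castrated label (n = 3 per group), with the same 2 of 3 wild-type libraries, the knockout was higher in Muc13, Ccl20 and Cp and lower in Sod1, Aldh6a1 and Bcat2. Muc13, a membrane mucin, had a log2 fold change of 10.43, Ccl20 9.37, Cp, the copper carrier ceruloplasmin, 5.08, Gpx2, a glutathione peroxidase, 4.06 and Phlda3, a p53 target, 3.21 (edgeR adjusted p = 0.0134, 0.0320, 0.00728, 0.0278 and 0.00734). Cdhr1, a cadherin, was at least 4052-fold higher (edgeR adjusted p = 0.0278). Sod1 (chromosome 16, 90220754 to 90226329), the cytosolic superoxide dismutase, lay at 213 ± 24.4 against 472 ± 79.2 CPM (log2 fold change -1.15 ± 0.17, edgeR adjusted p = 0.00261). Aldh6a1 at -2.67 and Bcat2 at -2.05, both enzymes of branched-chain amino acid breakdown, Colca2 at -3.11 and Pbsn at -9.30 were lower (edgeR adjusted p = 0.000391, 0.00760, 0.0308 and 0.0359). MHC class I genes had 0 of 9 past the test over all genes and 7 higher adjusted over the list alone (camera adjusted p = 3.61e-05, and adjusted p = 0.387 with an estimated correlation). Interferon genes had 0 of 19 past either adjustment, and seminal vesicle genes 0 of 8 over all genes and 7 lower adjusted over the list alone. Secretory genes were lower in 1 of 16 and 8 adjusted over the list alone, and inflammatory genes higher in 1 of 20 (Ccl20) and 4. Camera gave inflammatory genes adjusted p = 3.92e-09, and adjusted p = 0.246 with an estimated correlation. Of 17 leukocyte genes 0 passed over all genes and 2 were higher adjusted over the list alone (camera adjusted p = 0.00845, and adjusted p = 0.620 with an estimated correlation). EdgeR called 15 genes higher and 10 lower, and the total of 25 became 68, 4 and 8 without wild-type replicate 1, 2 or 3 and 13, 12 and 13 without knockout replicate 1, 2 or 3. DESeq2 gave 293 higher and 240 lower, and limma voom with quality weights 1265 and 909. Without the libraries of letters D and E it was 45.

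Whether the fractions differed in their response was tested with interaction terms in edgeR, and 5 of the 6 called 0 genes of 18222. The LY6D effect did not pass a difference between genotypes in hormone-sensitive libraries (915 genes at an unadjusted p under 0.05) or under the castrated label (786), nor between hormone labels in the wild type (1233) or the knockout (348). The castration effect did not pass a difference between genotypes in LY6D+ (1299), and in LY6D- 1 gene passed, 5430419D17Rik, named after its value was seen (log2 fold change -11.43 ± 1.76, edgeR adjusted p = 0.0222, with 1031 genes at an unadjusted p under 0.05). In the same order, DESeq2 called 146, 217, 315, 105, 348 and 209 genes and limma voom with quality weights 5, 2, 0, 61, 4 and 361. Without the castrated-labelled wild-type LY6D+ replicate 1, edgeR called 438 genes for the LY6D effect between genotypes under the castrated label, 572 for it between hormone labels in the wild type, and 607 for the castration effect between genotypes in LY6D+. The LY6D effect between hormone labels in the wild type called 1 without hormone-sensitive LY6D+ replicate 1 or castrated LY6D+ replicate 2, and 3 without hormone-sensitive LY6D+ replicate 2. The castration effect between genotypes called 2 in LY6D+ without wild-type hormone-sensitive or castrated replicate 2. In LY6D- it called 0 without any castrated knockout library, hormone-sensitive knockout replicate 1 or 3 or castrated wild-type replicate 2 or 3, 2 without hormone-sensitive wild-type replicate 2 and 4 without castrated wild-type replicate 1. In the same order as above, the fit without the 8 libraries of letters D and E called 34, 2, 10, 0, 45 and 7 genes, and the knockout libraries alone, with the same number as a block, 15 for the LY6D effect between hormone states; both were chosen after the data were seen. The counts of 0 therefore depend on the libraries and the model used, and passing the test in 1 setting and not in another does not by itself show a difference between them.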

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

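The tests of explanations in this part were all chosen after the results were seen, except the counts of other splits in the fit of 28 libraries, which were set before.

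Wild-type libraries of letters D and E showed androgen-regulated expression opposite to their hormone label. Scores used 159 lower and 55 higher genes shared by both knockout castration comparisons, without the seminal vesicle list. On them 8 of 8 such libraries lay opposite to the label, against 0 of the other 8 wild-type libraries. This restates the pattern with more genes and is no separate test of exchanged labels. Genes raised by castration were used to weigh seminal vesicle or secreted RNA carried over as the whole cause. By them 7 of the 8 lay opposite at the midpoint of wild-type libraries A to C, but only 3 of the 4 labelled hormone sensitive. A first midpoint from the knockout had left all 16 wild-type libraries on 1 side. The midpoint used has 1 castrated library per fraction, so the 4 labelled castrated stay open. Each of the other 4 had a higher mean of raised genes than all 3 A to C libraries of its label and fraction. This argues against carry-over there. Against low depth, 5 of the 8 opposite libraries had totals of 22111064 to 28647911 counts. An exchange of labels may explain the pattern. A different response to castration could not act in the 4 labelled hormone sensitive, where Svs2 lay at 0 to 1.77 CPM. Another biological difference stays open as untested.

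Basal epithelial transcripts were higher in LY6D+ libraries in each setting. Basal cells in the LY6D+ gate could account for it, as 13 of the 14 list members had a higher mean in LY6D+ in all 4 settings, though the YFP gate should remove cells without keratin 8 expression and Krt8 did not pass a fall in any setting, with log2 fold changes of 0.09 ± 0.29, -0.10 ± 0.38, 0.33 ± 0.38 and 0.05 ± 0.38. A lower share of luminal cells would raise markers of other cell types alike. In the paired knockout fit the basal median was 2.90, against 1.02 for fibroblast and smooth muscle, 0.72 for leukocyte and 0.42 for endothelial genes. The gap of 1.88 lay below the normal-scaled median absolute deviation of basal genes (2.17) but not the unscaled one. In the paired wild-type fit the basal median was 4.13, and the others were 3.45 for endothelial, 1.48 for fibroblast and smooth muscle and -0.13 for leukocyte genes, so 1 lay nearly as high and 2 did not, which leaves this open. Neither can be told apart from luminal cells that express basal genes, because bulk counts do not say which cells carried the transcripts.

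Seminal vesicle transcripts were higher in LY6D- than in LY6D+ libraries of hormone-sensitive knockout prostates. Free RNA added equally to both sorted fractions would give no difference, and the smallest median log2 difference of a pair of libraries was 3.45, with 3.90 and 4.73 in the others, which argues against it. One source of seminal vesicle RNA in both fractions would keep its genes in 1 ratio. In the knockout pairs, the only ones tested, the largest shift of a ratio was 0.88 in log2, which is what that needs. In the wild type labelled hormone sensitive the pair medians were 0.347, 3.28, 3.92, 0 and 0. In the knockout, unequal carry-over from 1 source may therefore contribute, and expression by the LY6D- cells themselves stays open.

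Among 45 tests for a library far from the other 4 of its group, 8 met the limit, where chance gives about 1 in 20 tests; each value is the gap to the nearest library over the range of the group. In wild-type LY6D+ labelled hormone sensitive, replicate 1 had 5.01% of counts from mitochondrially encoded genes against 1.58 to 2.26% (0.8), and 0.200 CPM of Sval1 against 0 (1). In the same group Olfm4 was 0.153 CPM in replicate 3 against 0 (1), Tbx3os1 42.9 CPM in replicate 2 against 20.6 to 23.3 (0.878) and Rasgrf1 89.8 CPM in replicate 5 against 18.0 to 33.9 (0.779). In LY6D- under the same label Pten was 39.1 CPM in replicate 5 against 15.6 to 21.2 (0.763), Ccl20 0.0477 CPM in replicate 3 against 0 (1) and Havcr1 0.130 CPM in replicate 1 against 0 (1). For Sval1, Olfm4, Ccl20 and Havcr1, with 4, 3, 1 and 3 counts in 1 library, the value of 1 follows from 0 counts in the others, so the share of 1 in 20 does not apply and these 4 show no unusual library. A difference between groups was called for 1 gene, 5430419D17Rik, in the castration by genotype interaction in LY6D-.

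Other splits of the same libraries give a measure of chance. In the fit of 28 libraries, of 56 splits 1 (the real one) gave as many genes as the 274 of the genotype comparison in LY6D+ under the hormone-sensitive label, where the highest other gave 53, so chance can be excluded there. For the 74 in LY6D-, 2 of 56 splits gave as many, a share under the limit of 0.05. The other split gave 94, more than the real one, and the count was 14 to 46 without any 1 of the 8 libraries. The share is therefore not read as excluding chance there. Chance can be excluded for the paired fits, where 1 of 128 splits gave the 39 genes of the wild type (highest other 2) and 1 of 32 the 1239 of the knockout (highest other 0), although the numbers of the hormone-sensitive knockout missed the bar set for pairs over all genes. It cannot be excluded for the LY6D comparison in the wild type labelled hormone sensitive, with 7 genes, as many in 9 of 100 splits and 433 at most, nor for castration in wild-type LY6D+ (1 gene, 43 of 56 splits, 933 at most) or LY6D- (0 genes, 56 of 56, 21 at most). Splits that call many times the real count, 433 and 933, point to a structure of these libraries other than their groups. For the interactions, 40 of 40 splits gave at least the real 0 in 5 of 6, with highest others of 0, 2, 67, 2 and 125 in the order given above, and 3 of 40 the real 1 in the sixth, with 24 at most. The genes higher in all 4 LY6D comparisons, and those lower, were 0 in 40 of 40 splits. As many gene list calls as the real 82 came in 5 of 40 splits (88 at most), so chance cannot be excluded for that number. Of the remaining comparisons each has 10 splits, too few for a share under 0.05. Their real counts and highest others were 0 and 278 for LY6D in the wild type labelled castrated, 0 and 0 in both knockout LY6D comparisons, 1 and 0 and 4 and 0 for castration in knockout LY6D+ and LY6D-, and 201 and 0 and 25 and 0 for genotype under the castrated label. In the knockout libraries alone, with 10 splits each, they were 941 and 0 and 236 and 4 for LY6D, and 382 and 0 and 1041 and 0 for castration.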

How the results depend on the processing

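Fits said here to be added, and the newer quasi-dispersion, were chosen after the data were seen. The wild type is WT, the knockout KO, hormone sensitive HS and castrated CR. No gene named by the rule or for a count of 5 or fewer changed sign under the alternatives run for it. Genes named from lists or paired fits were not checked. The balance of higher and lower genes turned in several counts. Higher and lower were 4 and 3 for LY6D in WT HS, against 47 and 130 without the 8 wild-type libraries D and E, and 7 and 11 without WT HS LY6D+ 4. For castration in WT LY6D+ they were 1 and 0, against 2 and 7 with the stricter filter, 0 and 1 with the replicate block, 184 and 487 with DESeq2, and 2 and 3, 1 and 7 and 2 and 6 without WT HS LY6D+ 1, 2 or 3; without WT CR LY6D+ 1, lower genes were also the more numerous of 1041. For genotype they were 65 and 9 in HS LY6D-, against 239 and 247 with DESeq2; 142 and 59 in CR LY6D+, against 123 and 175 without D and E; and 15 and 10 in CR LY6D-, against 29 and 39 and 1 and 3 without WT CR LY6D- 1 or 2. For castration by genotype in LY6D- they were 0 and 1, against 4 and 3 without D and E, 112 and 97 with DESeq2, and 1 and 0 with only the groups compared. The cause of a change was not tested except where the setting itself means fewer libraries or genes. Of the genes named by the rule or such a count, 119 kept their side of the threshold with RLE size factors and 2 lost it, against 118 and 3 with the 50 most abundant genes out, 97 and 24 with no filter, and 598 and 198 over the fits that leave out 1 library. With DESeq2 94 kept it and 27 gained it, and with limma voom with quality weights 68 kept, 16 lost and 37 gained it. With only the groups compared 42 kept, 38 lost and 40 gained it, with the replicate block 110, 9 and 2, with the block by title letter 54 kept and 24 lost it, and without libraries D and E (added) 85 kept, 17 lost and 19 gained it. Totals were 1739527 and 6127379 in WT CR LY6D+ 3 and 2, where 9336 and 8333 genes had at least 5 counts, against 16005 in the third library of that group, so depth limits how many genes are seen in those 2. The LY6D count in WT CR was 2 and 3 without them and 853 without WT CR LY6D+ 1, whose total was 18810130, so low depth is not shown to limit that count.

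Counts of genes that moved, by setting, were as follows. With RLE size factors: LY6D in WT CR 5. With the 50 most abundant genes out of library sizes: castration in KO LY6D+ 0. With no filter: LY6D in WT HS 2, castration in KO LY6D+ 0, genotype in HS LY6D+ 172, HS LY6D- 34, CR LY6D+ 119, CR LY6D- 13 and castration by genotype in LY6D- 0. With the stricter filter: LY6D in WT CR 9, castration in WT LY6D+ 9 and genotype in CR LY6D- 43. With the newer quasi-dispersion: LY6D in WT HS 101, WT CR 10, castration in WT LY6D+ 16, KO LY6D+ 3, KO LY6D- 8, genotype in HS LY6D+ 549, HS LY6D- 211, CR LY6D+ 422, CR LY6D- 155 and castration by genotype in LY6D- 9. With limma voom with quality weights: LY6D in KO HS 1520, KO CR 566, castration in WT LY6D+ 0, WT LY6D- 2, KO LY6D+ 565, KO LY6D- 1536, genotype in HS LY6D+ 1390, HS LY6D- 812, CR LY6D- 2174, LY6D by genotype in HS 5, CR 2, LY6D by castration in KO 61 and castration by genotype in LY6D+ 4, LY6D- 361. With DESeq2: LY6D in WT HS 404, WT CR 508, KO HS 172, KO CR 129, castration in WT LY6D+ 671, WT LY6D- 122, KO LY6D+ 173, KO LY6D- 227, genotype in HS LY6D+ 950, HS LY6D- 486, CR LY6D+ 1284, CR LY6D- 533, LY6D by genotype in HS 146, CR 217, LY6D by castration in WT 315, KO 105, castration by genotype in LY6D+ 348, LY6D- 209 and 3 higher in LY6D+ in all 4. With an estimated correlation there were 0 gene list calls of 82.

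With only the groups compared: LY6D in WT HS 1, KO HS 1295, castration in WT LY6D+ 0, KO LY6D+ 247, KO LY6D- 844 and genotype in HS LY6D+ 82, HS LY6D- 17, CR LY6D+ 2. With only the groups compared and a replicate block (added): LY6D in WT HS 0, KO HS 1270, KO CR 3. With the knockout libraries only (added): LY6D in KO HS 941, KO CR 236 and castration in KO LY6D+ 382, KO LY6D- 1041. With the knockout libraries only and a replicate block (added): LY6D in KO HS 1390, KO CR 252 and LY6D by castration in KO 15. Without the 8 wild-type libraries D and E (added): LY6D in WT HS 177, WT CR 3, KO CR 48, castration in WT LY6D+ 147, WT LY6D- 51, KO LY6D+ 70, KO LY6D- 147, genotype in HS LY6D+ 955, HS LY6D- 152, CR LY6D- 45, LY6D by genotype in HS 34, CR 2, LY6D by castration in WT 10 and castration by genotype in LY6D+ 45, LY6D- 7. With a replicate block, by pair for LY6D and by source-name number for castration and genotype: LY6D in WT HS 19, WT CR 1, KO HS 61, KO CR 4, castration in WT LY6D- 2, KO LY6D+ 6, KO LY6D- 45, genotype in CR LY6D+ 424, CR LY6D- 130, LY6D by castration in KO 1 and castration by genotype in LY6D- 2. With a replicate block by title letter: castration in WT LY6D- 1, KO LY6D+ 0, genotype in HS LY6D- 43, CR LY6D- 86 and castration by genotype in LY6D+ 1, LY6D- 3. In KO HS the library of the same number was the closest in 3 of 3, but correlations over all genes missed the bar set for pairs, and numbers did not match throughout across castration or genotype.

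Each library was left out in turn, and where an arm keeps 1 library its spread is assumed to be that of the other groups. The number of genes called for LY6D was 0 to 18 in WT HS (main 7), 0 to 853 in WT CR (main 0) and 0 to 2 in KO CR (main 0). For castration in WT LY6D+ it was 0 to 1041 (main 1), all by library in Results. For genotype in HS LY6D+ it was 92 to 278 (main 274), by library as in Results. For genotype in HS LY6D- it was 14 to 46 (main 74), by library as in Results. For genotype in CR LY6D+ it was 53 to 1383 (main 201), by library as in Results. For genotype in CR LY6D- it was 4 to 68 (main 25), by library as in Results. For LY6D by genotype in CR it was 0 to 438, and for LY6D by castration in WT 0 to 572 (main 0 in both). For castration by genotype it was 0 to 607 in LY6D+ (main 0) and 0 to 4 in LY6D- (main 1), all by library in Results. For gene list calls it was 71 to 91 (main 82). For castration in KO LY6D+ (main 1) and KO LY6D- (main 4) it was 0 to 0 without any 1 of the 6 libraries compared. For LY6D in KO HS, castration in WT LY6D-, LY6D by genotype in HS, LY6D by castration in KO, and the genes higher or lower in all 4, it was 0 to 0.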

Other observations

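MHC class II genes, which present antigen to CD4 T cells, lay higher after castration in both fractions of the knockout without passing the test over all genes. In the fit of the 12 knockout libraries, chosen after the data were seen, 0 of 7 were called over all genes and 7 of 7 adjusted over the list alone in LY6D+ and in LY6D- (camera adjusted p = 0.000455 and 0.00402, and adjusted p = 0.554 in both with an estimated correlation). H2-Ab1 lay at 539 ± 502 against 91.4 ± 37.0 CPM in LY6D- cells, castrated against hormone sensitive, and Cd74, the invariant chain, at 1650.3 ± 1746 against 255 ± 116 CPM (n = 3 per group). The leukocyte list had 0 of 17 members past either adjustment in both fractions, with medians of 0.92 in LY6D+ and 0.88 in LY6D- (camera adjusted p = 0.00191 and 0.0529, and adjusted p = 0.554 and 0.735 with an estimated correlation). Igkc, the immunoglobulin kappa constant gene, was higher in LY6D+ in 6 of 6 knockout pairs, at 519.7 ± 569 against 0.618 ± 1.31 CPM (log2 fold change 10.04 ± 1.94, edgeR adjusted p = 0.0215 in the paired knockout fit), and was singled out after its values were seen. Genes of protein folding and secretion in the endoplasmic reticulum fell after castration of knockout mice, 8 of 18 in LY6D- and 2 in LY6D+, and 16 and 7 adjusted over the list alone (camera adjusted p = 1.29e-10 and 3.39e-05, and adjusted p = 0.186 and 0.390 with an estimated correlation). Pdia6, a disulfide isomerase, had log2 fold changes of -1.05 and -0.77, and Manf, a secreted chaperone, -0.92 in LY6D-. The same list was lower in LY6D+ than LY6D- cells of the hormone-sensitive knockout, 5 of 18 over all genes and 10 adjusted over the list alone (camera adjusted p = 6.67e-09, and adjusted p = 0.188 with an estimated correlation).

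Mitochondrially encoded genes were lower in castrated knockout LY6D+ cells in 1 of 7 over all genes and 7 of 7 adjusted over the list alone, with a median log2 fold change of -0.64 (camera adjusted p = 6.43e-07, and adjusted p = 0.266 with an estimated correlation). Glutathione and xenobiotic genes fell in 4 of 14 and rose in 1, Aldh3a1, there. Cholesterol biosynthesis genes had a median log2 fold change of 0.97 between knockout and wild type in HS LY6D-. Of 20 genes 0 passed over all genes and 1 adjusted over the list alone (camera adjusted p = 1.29e-05, and adjusted p = 0.321 with an estimated correlation). FOXO target genes, which respond to PI3K signalling, had 0 of 14 past either adjustment in both hormone-sensitive genotype comparisons, and medians of -0.25 in LY6D+ and -0.19 in LY6D-. Proliferation genes had 0 of 22 past the test over all genes in each of the 12 comparisons of the fit of 28 libraries. Adjusted over the list alone, 1 was lower for castration in WT LY6D+ and 1 higher for genotype in HS LY6D+. They lay higher by camera for genotype in HS LY6D- and CR LY6D+ (medians 1.74 and 1.32). Camera adjusted p was 0.00135 and 0.0107, and adjusted p = 0.567 and 0.620 with an estimated correlation. In the paired wild-type fit camera gave adjusted p = 0.0254, and adjusted p = 0.487 with an estimated correlation.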
